A study of Mus musculus with 6 samples.

How the data were processed

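Poly(A) RNA of cultured mouse splenic B cells was measured in 6 libraries, 3 from wild-type mice and 3 labelled Wac conditional knockout, prepared with a kit that does not mark strand. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, Cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1, with the GRCm38 genome. The authors deposited 1 table with 51912 genes that holds a raw count and an FPKM value per gene and library, with gene lengths, symbols and annotation. The deposited FPKM values equalled the count divided by the exonic length in kilobases and scaled to the column total, to within 0.005, and were not used in any test. The strand setting of the counting is not given in the sources used here. Coordinates are those of the table. 99.5% of its gene identifiers were found in GENCODE M21, which gave biotypes, exon overlaps and GC content.

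From the counts, genes were kept with filterByExpr (minimum count 10, minimum total count 15), normalised with TMM and tested with edgeR 4.0.16 (quasi-likelihood F test with robust estimates, genotype as the only term, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. CPM values are scaled by the TMM library sizes. The SE of a log2 fold change is its size divided by the square root of F. Total counts ran from 14241564 to 17768896, and the precision is lowest for genes with few counts. All pairs of replicates differed by more than sampling noise (chi-square per degree of freedom of 2.01 or more over genes with a summed count of at least 20), so none was counted as a duplicate.

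A set of 37 gene lists was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 3 tested members. Named genes were the 12 highest and 12 lowest log2 fold changes among genes that passed, with a mean of at least 5 CPM and no overlap between groups, leaving out predicted and clone names, pseudogenes and immunoglobulin and T cell receptor segments, then 15 genes fixed by name, then up to 4 members of each list with the smallest adjusted p. The lists, the tests, the naming rule and the settings named next were set before the data were examined. These settings were RLE normalization, total count scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, leaving out immunoglobulin genes, a replicate block, leaving out each library, an estimated inter-gene correlation and fry. Corrections for gene length, and for gene length and GC content, were added after seeing the data, as per-library smooths (mgcv 1.9.3, genes above 3 log2 CPM) in the edgeR offsets. A correction for GC content alone was also run in the first look at the data and was not taken further. Figures were drawn with matplotlib 3.10.9.

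The steps were tested on simulated data, with 200 of 13917 genes changed between the 2 groups at the real means and dispersions. The edgeR step recovered 60% of the genes changed 1.5-fold and 83% of those changed 2-fold, and 7.14% of its calls were false. With a simulated gene length trend (13921 genes) 24.1% of calls were false, and 9.04% after the length correction. The simulated trend was linear with slopes set by hand, and both groups shared each gene's dispersion. In the data the biological coefficient of variation was 11.1% in wild type and 3.63% in the libraries labelled Wac cKO. The false-call rates therefore apply to the simulated settings and need not hold for these data.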

Results

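Gene expression was measured by poly(A) RNA sequencing in mouse splenic B cells that had been purified by removing CD43-bearing cells and cultured for 24 hours with lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4, at 20 µg/ml. The 6 libraries fell into 3 from wild-type mice and 3 labelled as Wac conditional knockout (cKO), in which a cre recombinase under Cd19 control deletes Wac in B cells. WAC is a WW domain adaptor protein that has been tied to histone H2B ubiquitination through RNF20 and RNF40, to p53 targets, autophagy, mTORC1 and mitosis. Total counts were 17768896, 15584286 and 14933742 in wild type replicates 1 to 3 and 15090216, 14241564 and 15752768 in the libraries labelled Wac cKO replicates 1 to 3. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

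The targeted gene went against its label. Wac (ENSMUSG00000024283, chromosome 18, 7868832 to 7973547 on GRCm38) was at 143, 162 and 169 CPM (counts scaled to library size) in wild type and at 206, 205 and 192 CPM in the libraries labelled Wac cKO, which is 158 ± 13.2 CPM in wild type and 201 ± 7.76 CPM in the libraries labelled Wac cKO (SD, n = 3 each). It was thus higher where it was expected to be deleted (log2 fold change 0.35, SE 0.08, adjusted p = 0.00799 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the call was lost without the library labelled Wac cKO replicate 2 (adjusted p = 0.0516). A count per gene adds up all exons, so loss of a deleted exon cannot be read from it. The annotated Wac exons also overlap an antisense gene, and the kit does not mark strand. How the counting treated reads in the overlap is not given, so the direction of any effect on the Wac count is not known. Because the deletion cannot be read from the counts, the group is called the libraries labelled Wac cKO throughout, and every direction below rests on that label. Cd19 (ENSMUSG00000030724, chromosome 7, 126408450 to 126414889), the gene that carries the cre allele and encodes a B cell co-receptor, was at 904, 947 and 913 CPM in wild type and at 494, 497 and 489.6 CPM in the libraries labelled Wac cKO (log2 fold change -0.90, SE 0.07, adjusted p = 8.92e-06). The Cd19 change and the Wac cKO label went together in every library, so they cannot be separated in this design. The groups are therefore compared by whole genotype and not by Wac alone. An effect of the genotype, as named below, includes the lower Cd19 level and any difference in the cre allele.

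**Figure D1:**
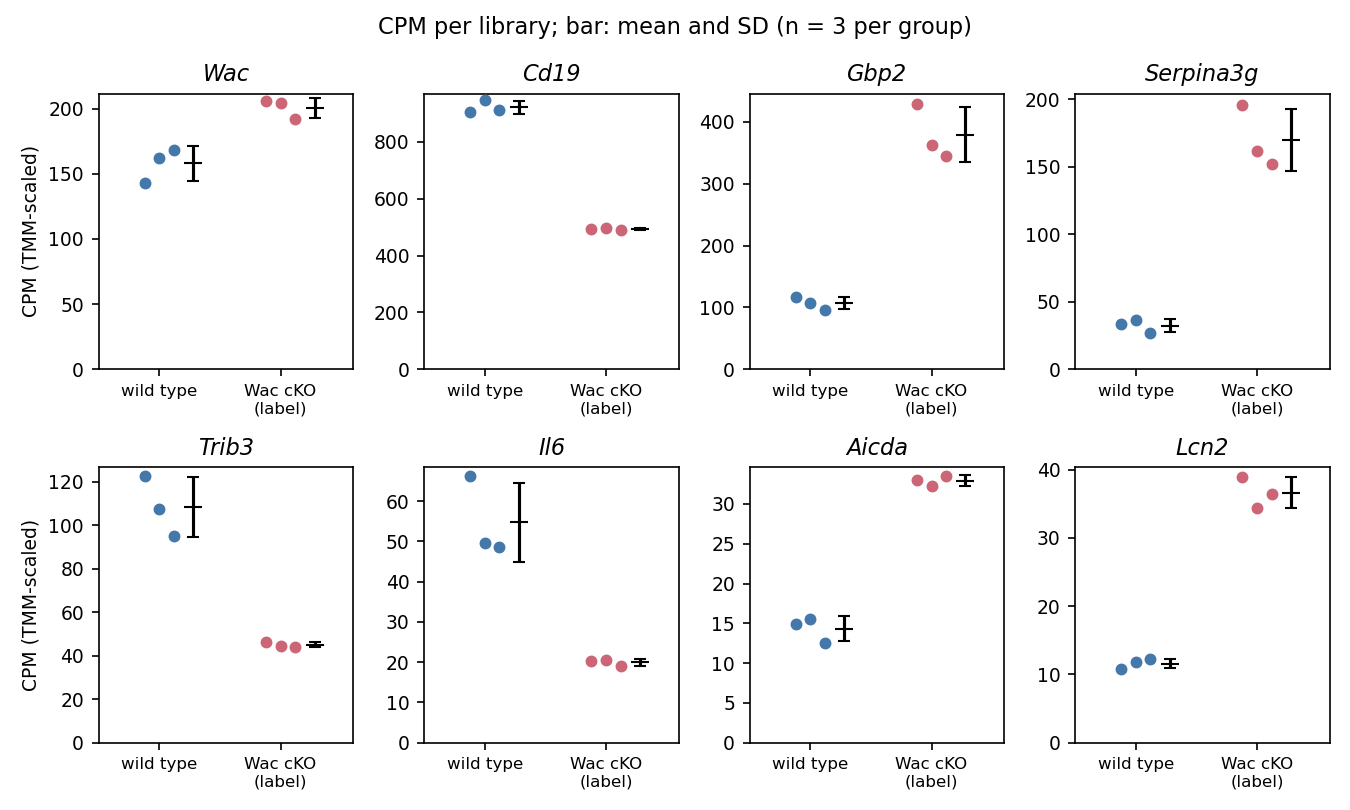
CPM (y axis, TMM-scaled, from 0) of 8 genes in each of the 3 wild type and 3 libraries labelled Wac cKO (x axis); points are libraries and bars the mean and SD. Cd19, Trib3 and Il6 were lower and Wac, Gbp2, Serpina3g, Aicda and Lcn2 higher in the libraries labelled Wac cKO, with no overlap between the groups.

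Of 14114 genes tested, 3645 changed at an adjusted p under 0.05, of which 1791 were higher and 1854 lower in the libraries labelled Wac cKO. Changes over 2-fold were mostly increases, with 440 genes higher and 114 lower among 554. With a gene length correction, chosen after seeing the data, 3581 genes changed, 2080.0 higher and 1501 lower, and 2769 of the 3645 calls were among them. The groups did not overlap for 44.9% of genes, where chance gives 10%. Leaving out a library changed the number of changed genes to 2059 without the library labelled Wac cKO replicate 1, 1719 without the library labelled Wac cKO replicate 2 and 1781 without the library labelled Wac cKO replicate 3.

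The highest log2 fold changes included interferon-inducible genes. Iigp1, an interferon-inducible GTPase, was at 1.33 ± 0.632 CPM in wild type and 23.8 ± 6.96 CPM in the libraries labelled Wac cKO (SD, n = 3 each; log2 fold change 4.13, SE 0.28, adjusted p = 5.10e-06). The serpins Serpina3f and Serpina3g had log2 fold changes of 3.12 (adjusted p = 4.73e-06) and 2.40 (adjusted p = 9.31e-07). Tgtp1 (2.72, adjusted p = 8.08e-05) and Tgtp2 (2.06, adjusted p = 8.29e-07) encode GTPases induced by interferon. Tbx21, which encodes the transcription factor T-bet, rose from 2.48 to 13 CPM (2.37, adjusted p = 9.17e-06). Thbs1 (1.94, adjusted p = 8.12e-06), Ms4a6b (1.88, adjusted p = 6.66e-07) and Gbp2 (1.83, adjusted p = 1.43e-06) were next. Chil3 (1.82, adjusted p = 4.26e-05), Ms4a4b (1.80, adjusted p = 3.89e-06) and Dnhd1 (1.79, adjusted p = 1.62e-05) completed the 12 highest. Serpina3f and Serpina3g, Tgtp1 and Tgtp2, and the Ms4a and Gbp genes are close paralogs. Reads that match several copies may be missing from their counts or assigned to the wrong copy. Thbs1, Ms4a6b and Gbp2 overlap annotated exons of a gene on the opposite strand, and Tgtp1 and Dnhd1 those of a gene on the same strand.

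Of 38 measured interferon response genes, 22 rose, 7 fell and 9 did not pass. 22 rose and 7 fell when adjusted over the list alone, with adjusted p = 4.09e-11 by camera and adjusted p = 0.241 with an estimated correlation. The members that rose included Irgm1 (1.15, adjusted p = 4.73e-06), Stat2 (1.04, adjusted p = 1.27e-05) and Ifit2 (0.98, adjusted p = 1.99e-05). The 7 that fell were also interferon-inducible: Oasl1, Isg20, Isg15, Ifit1, Ifih1, Ifi27l2a and Irf7, which were chosen for naming after their values were seen. Markers of other cell types moved with this group. Of 11 measured neutrophil markers, 9 rose, 0 fell and 2 did not pass. 11 rose and 0 fell when adjusted over the list alone, with adjusted p = 2.92e-18 by camera and adjusted p = 0.0371 with an estimated correlation. Lcn2, which encodes lipocalin 2, was at 11.6 ± 0.702 CPM in wild type and 36.6 ± 2.3 CPM in the libraries labelled Wac cKO (SD, n = 3 each). S100a9 was at a log2 fold change of 1.44 (adjusted p = 3.20e-05) and S100a8 at 1.55 (adjusted p = 4.56e-05). Of 17 measured macrophage and monocyte markers, 9 rose, 3 fell and 5 did not pass. 11 rose and 3 fell when adjusted over the list alone, with adjusted p = 0.00284 by camera and adjusted p = 0.202 with an estimated correlation. The estimate was -0.025 for this list and -0.031 for the marginal zone list given below, both under the preset 0.01. Both calls still ended in that setting. A call lost with an estimated correlation therefore cannot be put down to inter-gene correlation alone. Lyz2 (0.86, adjusted p = 9.11e-05), Ly6c2 (0.84, adjusted p = 3.26e-05) and Fcgr4 (2.21, adjusted p = 4.18e-04) rose, while Apoe (-1.11, adjusted p = 1.36e-05) fell. Ly6c2 is also a member of the plasma cell list. Of 11 measured erythroid and platelet markers, 6 rose, 0 fell and 5 did not pass. 8 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.00184 by camera and adjusted p = 0.226 with an estimated correlation. Alas2, of haem synthesis, was at 0.85 (adjusted p = 0.00118). Of 12 measured T cell markers, 3 rose, 0 fell and 9 did not pass. 3 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.0792 by camera. Of 5 measured NK cell markers, 2 rose, 0 fell and 3 did not pass. 2 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.0764 by camera.

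The lowest log2 fold changes were those of Ly6k (-2.76, adjusted p = 7.21e-06), Cox6a2 (-1.87, adjusted p = 2.07e-06), a cytochrome c oxidase subunit, and Angptl6 (-1.79, adjusted p = 3.20e-05). Next were Adm (-1.51, adjusted p = 5.01e-05), which encodes adrenomedullin, Atf5 (-1.46, adjusted p = 8.29e-07), a transcription factor of the stress response, and Il6 (-1.46, adjusted p = 1.84e-05), an inflammatory cytokine. Zbtb32 (-1.32, adjusted p = 2.76e-06), Soat2 (-1.31, adjusted p = 1.87e-05) and Trib3 (-1.27, adjusted p = 8.92e-06) followed. Vpreb3 (-1.23, adjusted p = 3.47e-05), Sdhaf1 (-1.21, adjusted p = 1.14e-04) and Fcmr (-1.15, adjusted p = 4.71e-06), the receptor for IgM, completed the 12 lowest. Cox6a2, Angptl6, Atf5, Ly6k and Sdhaf1 share exon positions with a gene on the opposite strand.

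ATF4 is a transcription factor induced by amino acid shortage and other stresses. Of 27 measured genes of the ATF4 amino acid response, 1 rose, 20 fell and 6 did not pass. 1 rose and 24 fell when adjusted over the list alone, with adjusted p = 4.34e-15 by camera and adjusted p = 0.0496 with an estimated correlation. Trib3, an ATF4 target, was at 109 ± 13.9 CPM in wild type and 45.1 ± 1.17 CPM in the libraries labelled Wac cKO (SD, n = 3 each), and Pycr1 (-0.94, adjusted p = 4.56e-05), Chac1 (-0.82, adjusted p = 1.25e-04) and Slc3a2 (-0.59, adjusted p = 2.44e-04) also fell. The member that rose was Slc7a11, the cystine transporter (0.87, adjusted p = 9.33e-04), named after its value was seen. Of 31 measured unfolded protein response genes, 0 rose, 16 fell and 15 did not pass. 0 rose and 22 fell when adjusted over the list alone, with adjusted p = 5.92e-08 by camera and adjusted p = 0.256 with an estimated correlation. Derl1 was at -0.65 (adjusted p = 2.50e-04) and Ddit3 at -0.70 (adjusted p = 3.52e-04). Trib3, Chac1 and Ddit3 belong to both lists. Of 39 measured MYC and ribosome biogenesis genes, 0 rose, 15 fell and 24 did not pass. 1 rose and 16 fell when adjusted over the list alone, with adjusted p = 0.00193 by camera and adjusted p = 0.304 with an estimated correlation. Myc itself (-0.38, adjusted p = 0.00361), Srm (-0.40, adjusted p = 0.00168), Rrs1 (-0.46, adjusted p = 0.00238) and Rrp9 (-0.39, adjusted p = 0.00496) fell.

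Of 39 measured mitosis genes, 21 rose, 1 fell and 17 did not pass. 21 rose and 2 fell when adjusted over the list alone, with adjusted p = 3.74e-06 by camera and adjusted p = 0.202 with an estimated correlation. Top2a, the DNA topoisomerase of dividing cells, was at 437 ± 18.4 CPM in wild type and 669.6 ± 11.7 CPM in the libraries labelled Wac cKO (SD, n = 3 each), and Cenpa (0.47, adjusted p = 0.00111), Knl1 (0.70, adjusted p = 0.00126) and Bub1 (0.38, adjusted p = 0.00398) rose as well. Of 79 measured ribosomal protein genes, 0 rose, 23 fell and 56 did not pass. 0 rose and 28 fell when adjusted over the list alone, with adjusted p = 2.70e-07 by camera and adjusted p = 0.674 with an estimated correlation. Their median log2 fold change was -0.30, and Rpl10a (-0.48, adjusted p = 6.63e-04) and Rpl41 (-0.55, adjusted p = 0.00642) were among those that fell. Of 71 measured oxidative phosphorylation genes, 0 rose, 11 fell and 60 did not pass. 0 rose and 6 fell when adjusted over the list alone, with adjusted p = 0.00104 by camera and adjusted p = 0.739 with an estimated correlation. The median of this list was -0.22, and Atp5g1 (-0.63, adjusted p = 0.00333) and Uqcrq (-0.43, adjusted p = 0.004) fell. The libraries also differed along gene length, which moved with these groups. Across genes, the Spearman correlation of a library's deviation with exonic length was -0.55 in wild type replicate 1, -0.29 in wild type replicate 2 and 0.12 in wild type replicate 3, and 0.33, 0.46 and 0.38 in the libraries labelled Wac cKO replicates 1 to 3, where genes are not independent replicates. With a gene length correction, chosen after seeing the data, 7 ribosomal protein genes fell, the list median was -0.13 and the list call stayed. For oxidative phosphorylation the same correction left 4 genes lower, a median of -0.01 and no list call (camera adjusted p = 0.405), while 24 mitosis genes rose. Without wild type replicate 1 the medians were -0.11 for ribosomal proteins and -0.04 for oxidative phosphorylation, whose list call ended (camera adjusted p = 0.275).

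**Figure D2:**
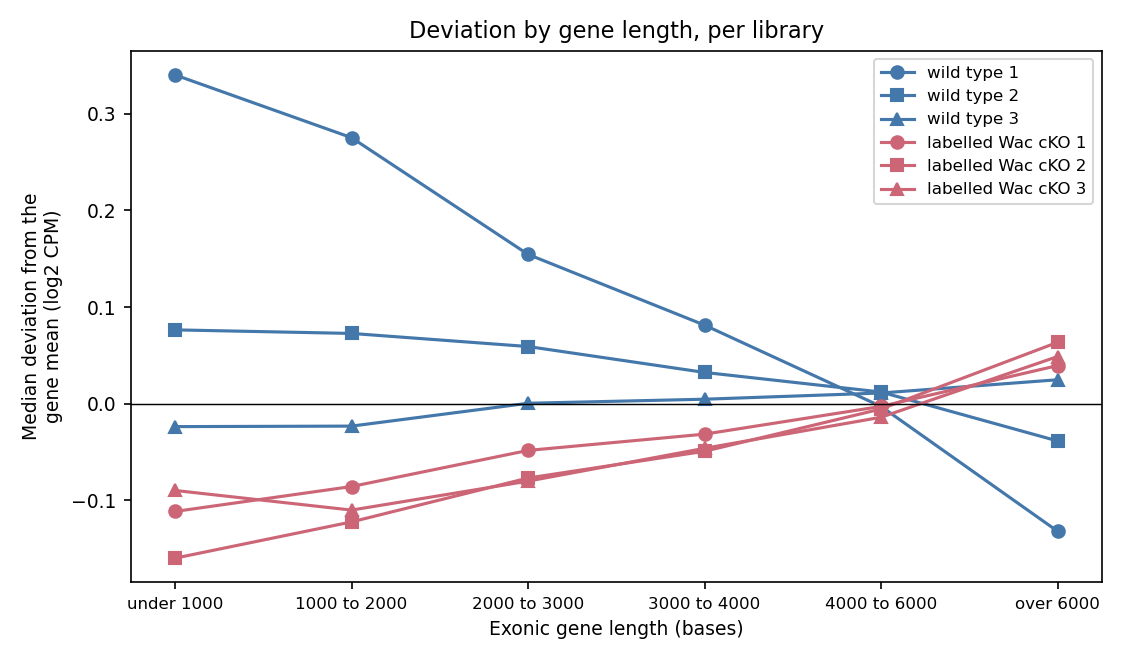
Median deviation of each library's log2 CPM from the gene's mean over the 6 libraries (y axis) in bins of exonic gene length (x axis, bases); each line is a library. In genes under 1000 bases, wild type replicate 1 lay at 0.34 and the libraries labelled Wac cKO between -0.16 and -0.09.

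B cell state genes changed in both directions. Of 20 measured marginal zone B cell genes, 2 rose, 10 fell and 8 did not pass. 3 rose and 11 fell when adjusted over the list alone, with adjusted p = 0.0335 by camera and adjusted p = 0.256 with an estimated correlation. The Notch targets Hes1 (-1.04, adjusted p = 0.00105) and Dtx1 (-0.48, adjusted p = 0.00313) fell, as did Dph5 (-0.53, adjusted p = 0.00146), and Notch2 rose (0.53, adjusted p = 0.00346). The marginal zone call was lost with the replicate block (adjusted p = 0.051), without wild type replicate 3 (adjusted p = 0.0874) and without the library labelled Wac cKO replicate 1 (adjusted p = 0.063). The Gene Ontology term marginal zone B cell differentiation, tested after the data were seen, pointed the other way. Among its 10 genes 5 rose and 0 fell (camera adjusted p = 0.0415, and 0.086 with a gene length correction). Of 14 measured follicular B cell genes, 3 rose, 4 fell and 7 did not pass. 3 rose and 4 fell when adjusted over the list alone, with adjusted p = 0.00465 by camera and adjusted p = 0.451 with an estimated correlation. Zbtb32, Fcmr and Vpreb3 were among those that fell, and Btg1 rose (0.52, adjusted p = 0.00262). That call ended with the gene length correction (camera adjusted p = 0.111) and with limma-voom (camera adjusted p = 0.15). Aicda, which encodes the deaminase of class switching and somatic hypermutation, was at 14.3 ± 1.6 CPM in wild type and 32.9 ± 0.646 CPM in the libraries labelled Wac cKO (SD, n = 3 each; log2 fold change 1.20, SE 0.10, adjusted p = 1.84e-05). Bcl6 (-0.56, adjusted p = 5.10e-04), Irf4 (-0.39, adjusted p = 0.00391), Xbp1 (-0.36, adjusted p = 0.00575), Prdm1 (-0.29, adjusted p = 0.0141) and Trp53 (-0.38, adjusted p = 0.00421) fell. The Prdm1 call was lost without any one of the libraries labelled Wac cKO replicates 1, 2 and 3 (adjusted p up to 0.0755). Bach2 (0.44, adjusted p = 0.00895) and Pax5 (0.27, adjusted p = 0.0215) rose, although Pax5 did not pass with the gene length correction (adjusted p = 0.0512) or without any one of the libraries labelled Wac cKO replicates 1, 2 and 3 (adjusted p up to 0.108). Jchain (-0.18, adjusted p = 0.327), Cdkn1a (0.13, adjusted p = 0.249), Rnf20 (0.11, adjusted p = 0.231) and Rnf40 (0.18, adjusted p = 0.156) did not pass.

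Immunoglobulin genes were summarised as groups, since a read may match several near-identical segments. All 4 Ighg constant genes measured rose, with a median log2 fold change of 0.55. Of 96 Igkv segments 1 rose and 38 fell, and 3 of 4 Iglc constant genes fell. Of 3 Iglv segments 3 fell, and of 93 Ighv segments 0 rose and 4 fell (median -0.02). These segments are short, and with the gene length correction 5 Igkv segments rose and 14 fell, with a median of -0.20 against -0.41 before. With it 11 Ighv segments rose and 0 fell (median 0.20), and 2 Iglc and 3 Iglv genes fell. Of 38 measured genes of B cell activation by LPS, 12 rose, 15 fell and 11 did not pass. 12 rose and 17 fell when adjusted over the list alone, with adjusted p = 0.932 by camera. The chemokine genes Ccl3 (1.11, adjusted p = 1.20e-05) and Ccl22 (0.98, adjusted p = 3.11e-05) were higher. Traf1 (-0.48, adjusted p = 4.29e-04) was lower, as was Il6.

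**Figure D3:**
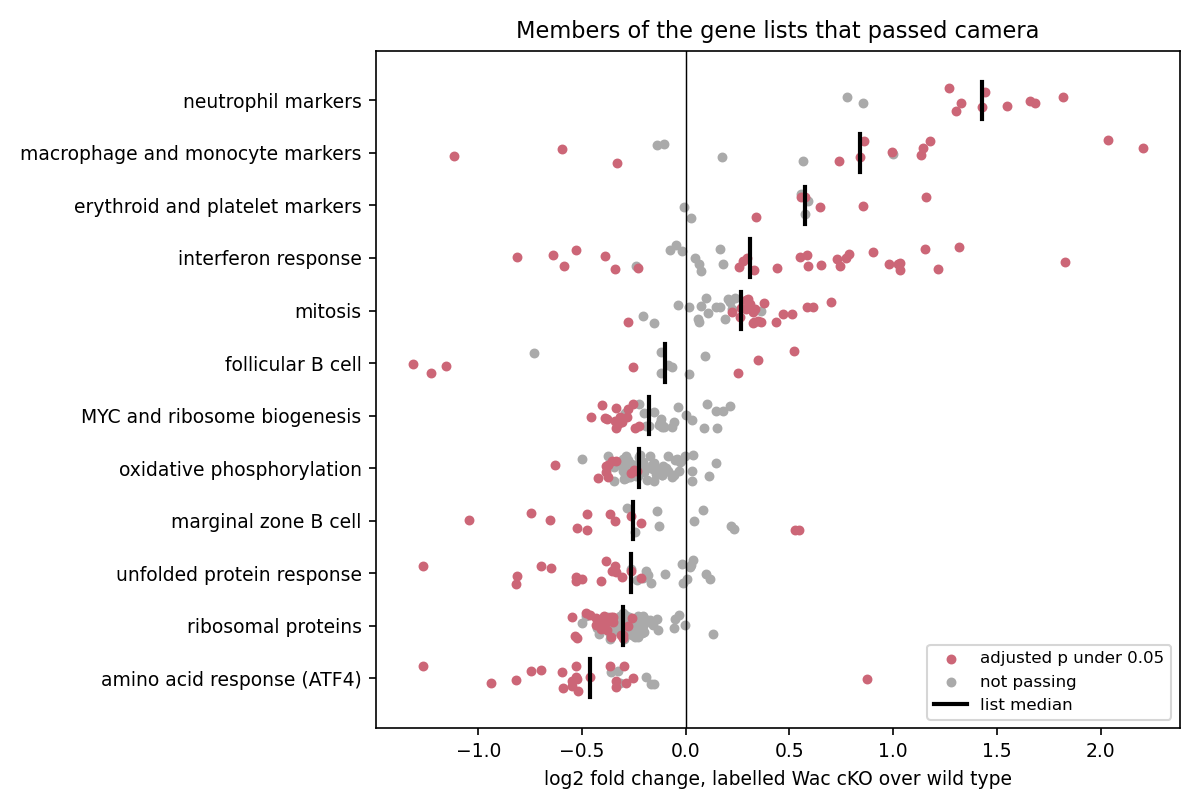
Log2 fold change (x axis, libraries labelled Wac cKO over wild type) of each measured member of the 12 gene lists that passed camera (y axis); points are genes, those in red at an adjusted p under 0.05, and the black bar is the list median. ATF4 genes lay at a median of -0.46 and neutrophil markers at 1.43.

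The other lists did not pass camera in the main fit, although some passed in other settings, given with the alternatives. Of 20 measured H2B ubiquitination genes, 2 rose, 3 fell and 15 did not pass. 2 rose and 3 fell when adjusted over the list alone, with adjusted p = 0.825 by camera. Wac was among the higher and Usp22 (-0.36, adjusted p = 0.00654) among the lower. Of 28 measured p53 targets, 5 rose, 5 fell and 18 did not pass. 5 rose and 5 fell when adjusted over the list alone, with adjusted p = 0.909 by camera. Gadd45a was lower (-1.04, adjusted p = 7.85e-05) and Trp53inp1 higher (0.63, adjusted p = 2.61e-04). Of 40 measured autophagy and lysosome genes, 1 rose, 7 fell and 32 did not pass. 1 rose and 7 fell when adjusted over the list alone, with adjusted p = 0.405 by camera. Sqstm1, the autophagy receptor, fell (-0.63, adjusted p = 9.86e-05). Of 25 measured mTORC1 and TTT-Pontin/Reptin genes, 1 rose, 7 fell and 17 did not pass. 1 rose and 7 fell when adjusted over the list alone, with adjusted p = 0.138 by camera. Eif4ebp1, a target of mTORC1, fell (-0.63, adjusted p = 5.85e-04). Of 27 measured plasma cell genes, 2 rose, 9 fell and 16 did not pass. 2 rose and 10 fell when adjusted over the list alone, with adjusted p = 0.129 by camera. Of 30 measured mature B cell identity genes, 5 rose, 6 fell and 19 did not pass. 5 rose and 6 fell when adjusted over the list alone, with adjusted p = 0.399 by camera. Of 33 measured germinal centre and class switching genes, 7 rose, 8 fell and 18 did not pass. 10 rose and 11 fell when adjusted over the list alone, with adjusted p = 0.909 by camera. Of 19 measured B1 and age-associated B cell genes, 7 rose, 2 fell and 10 did not pass. 7 rose and 2 fell when adjusted over the list alone, with adjusted p = 0.102 by camera. Of 26 measured Toll-like receptor signalling genes, 4 rose, 4 fell and 18 did not pass. 4 rose and 4 fell when adjusted over the list alone, with adjusted p = 0.909 by camera. Of 30 measured B cell receptor signalling genes, 7 rose, 3 fell and 20 did not pass. 7 rose and 4 fell when adjusted over the list alone, with adjusted p = 0.163 by camera. Of 40 measured DNA replication genes, 5 rose, 1 fell and 34 did not pass. 3 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.102 by camera. Of 25 measured cyclin and E2F genes, 3 rose, 1 fell and 21 did not pass. 2 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.425 by camera. Only 9 of 106 listed replication-dependent histone genes were measured in these poly(A) libraries, of which 0 rose, 3 fell and 6 did not pass. 0 rose and 4 fell when adjusted over the list alone, with adjusted p = 0.0938 by camera. Of 15 measured mitochondrially encoded genes, 0 rose, 1 fell and 14 did not pass. 0 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.399 by camera. Of 32 measured glycolysis and hypoxia genes, 4 rose, 5 fell and 23 did not pass. 4 rose and 5 fell when adjusted over the list alone, with adjusted p = 0.81 by camera. Of 23 measured cholesterol synthesis genes, 4 rose, 0 fell and 19 did not pass. 4 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.399 by camera. Of 25 measured apoptosis genes, 5 rose, 6 fell and 14 did not pass. 6 rose and 6 fell when adjusted over the list alone, with adjusted p = 0.909 by camera. Of 16 measured dissociation and immediate early genes, 2 rose, 1 fell and 13 did not pass. 2 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.684 by camera. Of 10 measured dendritic cell markers, 3 rose, 1 fell and 6 did not pass. 3 rose and 1 fell when adjusted over the list alone, with adjusted p = 0.825 by camera. Of 3 measured stromal markers, 1 rose, 0 fell and 2 did not pass. 2 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.0603 by camera. Of 4 measured sex-linked genes, 0 rose, 0 fell and 4 did not pass. 0 rose and 0 fell when adjusted over the list alone, with adjusted p = 0.684 by camera. Of the basophil and mast cell markers, only Kit (0.72, adjusted p = 8.46e-04) and Hdc (1.92, adjusted p = 0.00797) were measured, too few for a list test. For dendritic cell markers, the median (0.29) and the list test, which pointed down, differed in sign.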

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

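RLE normalization, total count scaling, both other filters, DESeq2, limma-voom, leaving out immunoglobulin genes and both corrections added after seeing the data kept Cd19 lower, Wac higher and each count of genes within 1.5 times its value. Leaving out 1 library gave 1719 to 4548 changed genes, 915 to 2188 higher and 804 to 2360.0 lower, the smallest counts each without the library labelled Wac cKO replicate 2. The largest counts were each without wild type replicate 1. The spread between libraries was unequal. The biological coefficient of variation was 11.1% in wild type, 5.74% in wild type replicates 2 and 3, and 3.63% in the libraries labelled Wac cKO. Its part in these counts was not tested. The Wac log2 fold change ran from 0.276 to 0.397, and it did not pass without the library labelled Wac cKO replicate 2. Of 12 gene lists that passed camera, 2 passed with an estimated correlation (neutrophil and ATF4 lists). Calls ended at estimates of -0.031 (marginal zone) to 0.86 (ribosomal proteins). In all, 18 lists passed fry, which does not compare a list with other genes: 10 of the 12 and 8 that did not pass camera (autophagy and lysosome, mTORC1 and TTT-Pontin/Reptin, plasma cell programme, B1 and age-associated B cell, DNA replication, T cell markers, NK cell markers, stromal markers). Camera calls absent from the main fit appeared in these settings: no filter on low counts (mTORC1 down, T cell markers up, basophil and mast cell markers up); without wild type replicate 1 (DNA replication up); without the library labelled Wac cKO replicate 2 (T cell markers up, NK cell markers up, stromal markers up); without the library labelled Wac cKO replicate 3 (B1 up, stromal markers up); gene length correction (plasma cell programme down, DNA replication up, T cell markers up, NK cell markers up); gene length and GC correction (plasma cell programme down, DNA replication up); limma-voom (DNA replication up, T cell markers up, NK cell markers up). The ribosomal protein and oxidative phosphorylation lists did not pass fry (adjusted p = 0.207 and 0.301). Deviations of same-numbered libraries correlated at 0.050, 0.050 and 0.031, the best match for numbers 1 and 2 only. With 3 libraries per group this cannot decide on pairing. The replicate block gave 3654 changed genes, 1818 higher and 1836 lower, with Wac at 0.35 and Cd19 at -0.90. Over named genes and settings, 18 calls ended and 18 appeared, and 90 ended and 6 appeared with a library left out. Signs turned in results that passed the threshold under neither setting, with median log2 fold changes for lists (whose direction is that of camera) and the cause not tested. With gene length correction: mt-Nd6 0.0434, mt-Atp6 0.0204, Kdm5d -0.133, Uty -0.0512, the p53 targets list 0.0885, the toll-like receptor signalling list 0.0238, the mitochondrially encoded list 0.115, the apoptosis list 0.0114, the sex-linked list -0.0441. With gene length and GC correction: mt-Nd6 0.0993, mt-Atp6 0.0425, Kdm5d -0.129, Uty -0.0232, the p53 targets list 0.0857, the mitochondrially encoded list 0.101, the apoptosis list 0.0167. With limma-voom: the p53 targets list 0.0123, the B cell activation by LPS list -0.0292, the dendritic cell markers list 0.293. With no filter on low counts: the B cell activation by LPS list -0.051. With replicate block: the B cell activation by LPS list -0.0293. With DESeq2: the B cell activation by LPS list -0.0204. Leaving out 1 library turned signs within these ranges: Jchain -0.284 to 0.00841, Kdm5d -0.0119 to 0.131, Ddx3y -0.136 to 0.0402, the p53 targets list 0.0344 to 0.0664, the B cell activation by LPS list -0.0879 to -0.00419, the toll-like receptor signalling list -0.0904 to 0.0257, the glycolysis and hypoxia list 0.0213 to 0.115, the apoptosis list -0.0483 to -3.17e-04, the dendritic cell markers list 0.203 to 0.301. Depth limits the lowest genes, such as Ifng at under 3 CPM.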

Other observations

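Gene Ontology biological process terms from the deposited annotation were tested with camera after the data were seen, and in this part the tests of the interferon genes, of gene length and of the Wac transcript were also chosen after the result was seen. Of 1549 terms with 10 to 300 tested genes, 97 passed as higher and 16 as lower in the libraries labelled Wac cKO, and 45 passed in the same direction after the gene length correction. Without wild type replicate 1 many of the 113 calls ended, in both directions. Among them were cell adhesion (higher, camera adjusted p = 0.174), cytoplasmic translation (lower, camera adjusted p = 0.391) and mitochondrial respiratory chain complex I assembly (lower, camera adjusted p = 0.175). The terms named next also passed without that library. Migration terms were among the higher ones: neutrophil chemotaxis (21 of 38 genes higher and 1 lower, adjusted p = 3.19e-12, 2.07e-14 after the length correction) and lymphocyte chemotaxis (7 of 10 genes higher and 0 lower, adjusted p = 3.86e-06, 2.14e-08 after the length correction). The lower term with the smallest adjusted p was translation (2 of 140 genes higher and 35 lower, camera adjusted p = 2.78e-05). It passed after the length correction (0.0165) and without wild type replicate 1 (0.00758). Also among the lower ones were methylation (0 of 42 genes higher and 13 lower, adjusted p = 0.0105, 0.00732 after the length correction), tetrahydrofolate interconversion (0 of 10 genes higher and 4 lower, adjusted p = 0.0228, 0.0165 after the length correction) and regulation of translational fidelity (0 of 15 genes higher and 7 lower, adjusted p = 0.0282, 0.00934 after the length correction). Ifng, which encodes interferon-gamma, was at 0.266 ± 0.117 CPM in wild type and 1.77 ± 0.535 CPM in the libraries labelled Wac cKO (SD, n = 3 each; log2 fold change 2.68, SE 0.41, adjusted p = 0.00111 by edgeR), and Ighg1 rose from 1.46 to 6.89 CPM (2.23, adjusted p = 2.04e-05).

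Of 38 interferon response genes, 22 were higher and 7 lower in the libraries labelled Wac cKO, and the list call ended with an estimated correlation (adjusted p = 0.241). For the 22, a gene length trend as the whole source is argued against by the length correction, after which 22 of the 22 still rose. Transcripts brought in by T, NK, macrophage or neutrophil cells stay open: the summed CPM rise of 23 called markers was 0.0896 times that of these 22 (153 against 1703 CPM), but the tables do not give the levels of interferon genes in those cells. The removal of CD43-bearing cells should have taken out most of them, and its purity is not given. Interferon-gamma released by other cells in the culture may contribute and stays open: the Ifng log2 fold change was 2.68 against a median of 0.448 for T and NK cell markers, and the source cell is not known. An effect of the genotype also stays open, as untested.

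Of 79 ribosomal protein genes 23 were lower, and of 71 oxidative phosphorylation genes 11, with list calls that ended with an estimated correlation (adjusted p = 0.674 and 0.739). The lists have median lengths of 1734 and 1552 bases, and a gene length trend is a candidate explanation. With the trend fitted without these genes, the list medians moved from -0.303 to -0.129 and from -0.223 to -0.0131, and 7 of 23 and 4 of 11 members still fell. By camera with the length correction, the ribosomal protein call stayed and the oxidative phosphorylation call ended. The test of wild type replicate 1 as the source, chosen once that library was seen to stand apart but before the result without it was seen, asked whether the calls stay without it, and 23 of 23 and 11 of 11 did. The medians of these called genes were -0.236 and -0.23 without it, against -0.378 and -0.372 with it. For these called genes a fall thus remained without that library. They were chosen for passing in a fit that shared the other libraries, so their calls were likely to stay. The test therefore cannot decide on that library as a source for the lists as a whole. Over all members the medians without it were -0.107 and -0.0427. An effect of the genotype stays open.

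The Wac transcript was higher where it was expected to be lower. A swap of the group labels is argued against by Cd19, whose lowest wild type value was 1.82 times its highest value in the libraries labelled Wac cKO. A gene length trend is argued against as the source, since the Wac log2 fold change was 0.32 after the length correction against 0.345 before. Reads from exons outside a deleted part were not tested, because there is 1 count per gene.

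The Wac and Cd19 loci were checked for sequence carried along with an engineered allele, with tests chosen with the data in hand but before their results were seen. Within 5 Mb of Wac, 7 of 35 genes changed, against 25.8% elsewhere (one-sided Fisher's exact p = 0.837). Within 5 Mb of Cd19, 42 of 147 changed, against 25.8% elsewhere (one-sided Fisher's exact p = 0.248). No excess was detected at either locus, and a small one is not excluded. For the counts of genes, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, the counts reached 3645 changed, 1791 higher, 1854 lower and 554 over 2-fold, and the highest of the other splits was 0 for each. Each other split put libraries of both groups on each side, so any group difference added to the spread within a side. Their counts were thus likely to be low, and the splits cannot decide whether the real counts arose by chance.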
